A study of Methanosarcina acetivorans C2A with 15 samples.

How the data were processed

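Per the sample labels, total RNA was isolated with TRIzol and a column kit, 16S and 23S rRNA were subtracted with biotin-labeled probes, and indexed libraries were made with the ScriptSeq v2 kit. The libraries were sequenced on a HiSeq2000, and reads were demultiplexed with Casava 1.8.2. The labels give the growth stage as mid-exponential in one protocol and early exponential in another. The aligner, its version, the genome build and the use of read strand in counting were not given in the sources used here, so reads from overlapping or antisense genes cannot be assigned with certainty. Per the file headers, the counted reads were trimmed single reads that an earlier mapping, not described further, had left unmapped.

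The authors deposited 2 tables with the same 4725 features, 1 for the 9 wild-type libraries and 1 for the 6 libraries of the strain comparison. The total gene reads are counts deposited by the authors, raw and including reads with several matches, and all tests below start from them. The unique gene reads are counts, per the file headers, of reads with a single match, and served as an alternative. The deposited RPKM values were scaled by the authors by gene length and by the reads of each library, and served as an alternative too. The deposited p-values come, per the file headers, from the authors' own test with tagwise dispersions and are unadjusted. The score columns hold the authors' signed fold change, deposited as the second group named over the first. The authors' p-values and fold changes entered no test here, and the normalized values deposited by the authors were not used as the main measure.

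Names and positions are those of the deposited tables. Of the 4725 features, 3333 were matched to the reference annotation (assembly ASM734v1, used for names and products) by old locus tag, 752 by both ends and 228 by 1 end, and 412 by none. Features annotated as rRNA (9) or tRNA (59) were left out of the tests and kept in an alternative. Genes with low counts were removed with the filterByExpr function of edgeR at a minimum count of 10. Library sizes were scaled by the trimmed mean of M-values (TMM).

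Groups were compared with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), in 1 fit per table with a mean per group. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. Every adjusted p of a gene below comes from this test. Levels are counts per 1e6 (CPM) of the TMM-scaled library size, as mean ± SD over libraries. Log2 fold changes are the first group named minus the second, with a standard error (SE). The SE was derived as the absolute log2 fold change divided by the square root of the F statistic. The 2 tables were normalized and fitted apart, so levels from one cannot be compared with levels from the other. DESeq2 1.42.0 and limma 3.58.1 were used in alternatives.

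The tests of the comparisons, most alternatives and 23 gene lists were chosen before the data were examined, and those added later are named as such. The lists cover the mts methyltransferases, the mtp locus, methanol methyltransferases, methylamine methyltransferases, methyl-coenzyme M reductase, the Mtr methyltransferase, methyl oxidation, the Fpo dehydrogenase, the Rnf complex, heterodisulfide reductase, ATP synthase, CO dehydrogenase and acetate genes, ribosomal proteins, nitrogen fixation, chaperones and heat shock, transposases, sulfur amino acid genes, corrinoid synthesis and transport, iron transport, oxidative stress, phosphate transport, archaellum and chemotaxis, and HTH regulators. They were defined by product words, gene symbols and locus tags. Genes were then matched by symbol or locus tag, so a list need not hold every gene with such a product. The members of the lists were resolved from the annotation after the abundance of some genes had been seen and before any test was run. Lists of at least 3 tested genes were tested with camera of limma, at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Their p-values were adjusted over the lists within a comparison.

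Named genes followed a rule set before the data were examined. The rule takes the members of the first 4 lists, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 50 CPM and no overlap between groups, the 2 members with the largest change of each other passing list, the deleted genes, and the 5 largest of each shared or specific set. Genes named outside this rule are marked as chosen after their values were seen.

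In a test of the pipeline, 200 genes were changed in simulated libraries, 100 by 2-fold and 100 by 4-fold. Each gene had the spread fitted to the real libraries, the same in all groups. At 2-fold, 82% were recovered for MMPA against methanol, 24% for DMS against methanol, 48% for MeSH against methanol, 28% for DMS against MMPA and 75% for the strain comparison. At 4-fold the shares were 98%, 83%, 89%, 88% and 95%. False calls made up 8.16%, 5.31%, 2.84%, 5.69% and 5.03% of calls. The real DMS libraries agreed less with each other (Spearman's rho 0.797) than the MeOH libraries did (at least 0.986). The shares for DMS, and for the lone MeSH library, may therefore not hold for the real libraries.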

Results

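RNA sequencing measured transcript levels in *Methanosarcina acetivorans*, a methane-producing archaeon, grown on methylated sulfur compounds or on methanol. The wild-type strain WWM604 was grown on 20 mM methylmercaptopropionate (MMPA; 3 libraries), dimethyl sulfide (DMS; 2 libraries, at 9 and 20 mM), 10 mM methanethiol (MeSH; 1 library) or 125 mM methanol (MeOH; 3 libraries). A strain with msrH deleted (WWM833; 3 libraries) and its parent (WWM82; 3 libraries) were both grown on 5 mM trimethylamine with 20 mM MMPA. The labels give hpt as deleted in both strains, and name an integrase cassette at hpt for the parent alone.

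Total gene counts were 4932636, 4064057 and 2726141 in the MMPA libraries, 1326318 and 819588 in the DMS libraries and 4944259 in the MeSH library. The MeOH libraries held 9576835, 9167619 and 10504244 counts. The msrH deletion libraries held 6384652, 7259057 and 6213273 counts, and the parent libraries 6905850, 15482840 and 7709717. The median gene had 4 counts in DMS replicate 2, where 840 genes had none, against 94 counts in DMS replicate 1. Nothing in the labels states that replicates came from separate cultures, so the p-values may measure technical spread alone. All MeOH libraries carry a different name series and lane code from the other wild-type libraries, so growth on methanol and library series cannot be told apart.

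The comparison of MMPA with MeOH asks which genes set growth on MMPA apart. On MMPA 2 genes of the mtp locus rose most of all genes tested: MA4164 was 172-fold higher (14059 ± 9516 against 81.8 ± 2.17 CPM, SD, n = 3 each), with a log2 fold change of 7.43 (SE 0.85, adjusted p = 0.000269). Its neighbour cmtA (MA4165) was 151-fold higher, at 23347 ± 16460 against 154 ± 5.21 CPM (log2 7.24, SE 0.94, adjusted p = 0.000444). MA4166, which follows on the chromosome, rose 56.3-fold (log2 5.82, SE 0.82, adjusted p = 0.000607), while MA4167 of the same locus did not pass (log2 -0.12, SE 0.14, adjusted p = 0.455). The methanol methyltransferase genes split: mtaC3 rose 79.0-fold and mtaB3 57.2-fold, to 6707 ± 1162 from 117 ± 5.85 CPM, while mtaB1 was 41.4-fold lower, at 70.3 ± 3.97 against 2910 ± 887 CPM. The gene beside the mtaB1 pair, MA0457, had the lowest log2 fold change among the genes the naming rule took, at -5.53 (SE 0.33), next to mtaC1 at -5.47 (SE 0.51). The mtp genes lie at 5084184 to 5084978 (MA4164), 5085048 to 5086082 (cmtA) and 5086373 to 5087707 (MA4166) on the chromosome, in the coordinates of the deposited tables.

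The methyltransferases of methylated sulfur compounds also rose on MMPA. MA4384 (mtsF) was 19.6-fold higher (4522 ± 4620 against 230 ± 20.0 CPM, adjusted p = 0.00353), MA0859 (mtsD) 15.9-fold (adjusted p = 0.00665) and MA4558 (mtsH) 8.15-fold (adjusted p = 0.0151). The SD of these genes on MMPA was near or above their mean, as replicate 1 held 9722 CPM of MA4384 and replicate 3 held 889. Without MMPA replicate 1, the log2 fold changes were 3.16 for MA4384, 2.73 for MA0859 and 2.20 for MA4558, the last with an adjusted p of 0.0506. MA4558 also missed the threshold without MeOH replicate 2 (adjusted p = 0.0502) or MeOH replicate 3 (adjusted p = 0.0515). Of the methylamine methyltransferase genes, mtmC1 rose by 3.01 (log2, SE 0.41), mtmB1 by 2.69 (SE 0.37), mtbA_1 by 2.34 (SE 0.57), mttC_1 by 1.92 (SE 0.27), mttB_1 by 1.83 (SE 0.27), mtbC_1 by 1.72 (SE 0.27) and mtbB_1 by 1.03 (SE 0.34). In the same list, mtbC_2 (0.59), mtbA_2 (0.41) and mtmB2 (-0.39) changed little, and mtbC_2 and mtbA_2 turned negative on the RPKM scale, as did mtaA_1 (0.48). The median of all genes moved from -0.10 to -0.73 there, as far as these genes did, so the signs follow the scaling. The gene next to mtaB3, cmtM_2 (MA1615), rose 10.2-fold.

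Some genes of acetyl-CoA, methane and energy metabolism were also higher on MMPA, though none of their lists passed camera with an estimated correlation (lowest adjusted p = 0.453). The second copy of the CO dehydrogenase genes was among the highest, with cdhE_2 29.3-fold higher (4638 ± 1581 against 158 ± 38.7 CPM, adjusted p = 8.65e-05), cdhC_2 at log2 4.86 and cdhB_2 at log2 4.40. Methyl-coenzyme M reductase, the methane-forming enzyme, was led by MA4548 (log2 3.35, SE 0.81) and MA4549 (log2 3.29, SE 0.71). Both stood lower in MMPA replicate 3, with MA4548 at 4309 CPM there against 24392 and 22055 in replicates 1 and 2. The cysteine synthase gene cysK rose 12.7-fold, and MA2718 by 3.08 (log2). Further named genes that rose were hdrC_2 (log2 2.63), hdrB_2 (1.71), fpoF (2.58), fpoC (2.20), mtd (2.24), fmdD_1 (2.29), atpH (2.10), MA2441 (2.16), ahpC (2.82), sodB (2.70), rpl39e (2.03), rplX (1.90), mtrF (1.23), mtrA (1.04), MA0665 (1.41), nqr6 (1.26) and mcp-2 (0.75). MA3302 (log2 5.37, SE 0.64) and MA0849 (log2 5.21, SE 0.61) were also among the 8 highest the naming rule took. After the mtaB1 group, the lowest the naming rule took were MA4243 (-1.60), MA4242 (-1.58), MA4244 (-1.52), MA0387 (-1.47) and MA4534 (-1.46), and pstC_1 (-1.08), pstC_2 (-0.93) and cheW1 (-0.90) were lower in their lists.

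Of 4627 genes tested, 1233 were higher and 1404 lower on MMPA, 739 and 258 of them by at least 2-fold. The median log2 fold change of all genes was -0.10, and it moved to -0.39 with upper-quartile normalization, where 882 were higher and 2043 lower. The majority was higher instead with the 2 groups alone (1505 against 1312), with MA3471 and MA4588 removed (1382 against 1065), and without DMS replicate 2 (1503 against 1317), MMPA replicate 1 (1173 against 818) or MMPA replicate 2 (1078 against 637), as it was with a test against 2-fold (303 against 20) and on the RPKM scale (36 against 4). Without MeOH replicate 3 the count fell from 2637 to 1696, and without MMPA replicate 2 to 1715. Of the 65 named genes past the threshold, 56 kept their call whichever library was left out. The exceptions were MA4558, MA0665, mcp-2, mtaA_1, mtbA_2, mtbB_1, mtmB2, mtrA and mtrF. With MMPA replicate 1 left out, mtbB_1 had an adjusted p of 0.0592, mtmB2 of 0.189, mcp-2 of 0.0525 and mtrA of 0.0680. With MMPA replicate 2 left out, the adjusted p was 0.0765 for mcp-2, 0.0548 for mtaA_1, 0.0857 for mtbB_1, 0.254 for mtmB2 and 0.0673 for mtrA. With MMPA replicate 3 left out, that of mtbA_2 was 0.0606. With MeOH replicate 1, 2 or 3 left out, 8, 6 and 9 of the 65 calls were lost, among them MA0665 (0.0567 without replicate 1) and mtrF (0.0540).

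By list, all 3 mts methyltransferases, 3 of 4 genes of the mtp locus, 5 of 5 of methyl-coenzyme M reductase, 6 of 8 of the Mtr methyltransferase, 8 of 8 of the Rnf complex, 11 of 11 of ATP synthase and 15 of 16 CO dehydrogenase and acetate genes were higher, over all genes and adjusted over the list alone. Higher genes numbered 11 of 15 for the Fpo dehydrogenase (13 adjusted over the list alone), 4 of 9 for heterodisulfide reductase (4 adjusted over the list alone) and 23 of 46 ribosomal proteins (21 adjusted over the list alone). Methyl oxidation had 17 higher and 5 lower of 25, methylamine methyltransferases 9 and 1 of 18, methanol methyltransferases 4 and 2 of 9, and oxidative stress 5 and 1 of 7, each with the same counts adjusted over the list alone. Sulfur amino acid genes had 7 higher and 1 lower of 10 (7 and 2 adjusted over the list alone), and chaperones and heat shock 7 and 1 of 14 (8 and 1 adjusted over the list alone). Phosphate transport had 6 of 8 lower (7 adjusted over the list alone), archaellum and chemotaxis 16 lower and 2 higher of 25 (16 and 2 adjusted over the list alone), and iron transport 4 of 7 lower (5 adjusted over the list alone). Nitrogen fixation had 6 higher and 14 lower of 35, and transposases 17 and 11 of 60, each with the same counts adjusted over the list alone. Corrinoid synthesis and transport had 7 higher and 8 lower of 34 (6 and 8 adjusted over the list alone), and HTH regulators 3 and 2 of 10 (3 and 1 adjusted over the list alone).

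Tested against other genes with camera, 13 lists were higher and 2 lower on MMPA, led by CO dehydrogenase and acetate genes (adjusted p = 4.84e-08), ribosomal proteins (3.68e-06) and ATP synthase (0.000478). None of the 15 held with an estimated correlation, where the lowest adjusted p was 0.453, and fry called 14 lists. Heterodisulfide reductase also missed the threshold without MMPA replicate 1 (0.0935). The lists that passed were also the mtp locus (0.0152), the Mtr methyltransferase (0.0152), methyl-coenzyme M reductase (0.0162), methylamine methyltransferases (0.0201), methyl oxidation (0.0104), the Fpo dehydrogenase (0.00844), the Rnf complex (0.0103), heterodisulfide reductase (0.0304), sulfur amino acid genes (0.0113) and oxidative stress (0.0209), with archaellum and chemotaxis (0.00797) and phosphate transport (0.0253) lower. The mts methyltransferases did not pass camera (0.0683), nor did methanol methyltransferases (0.334), chaperones and heat shock (0.0557), nitrogen fixation (0.194), transposases (0.537), corrinoid synthesis and transport (0.912), iron transport (0.118) or HTH regulators (0.821). Fry's 14 lists left out ribosomal proteins (fry adjusted p = 0.0859), the Mtr methyltransferase (0.0616) and the Fpo dehydrogenase (0.102). They took in the mts methyltransferases (fry adjusted p = 0.0489) and iron transport (0.0242).

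**Figure D1:**
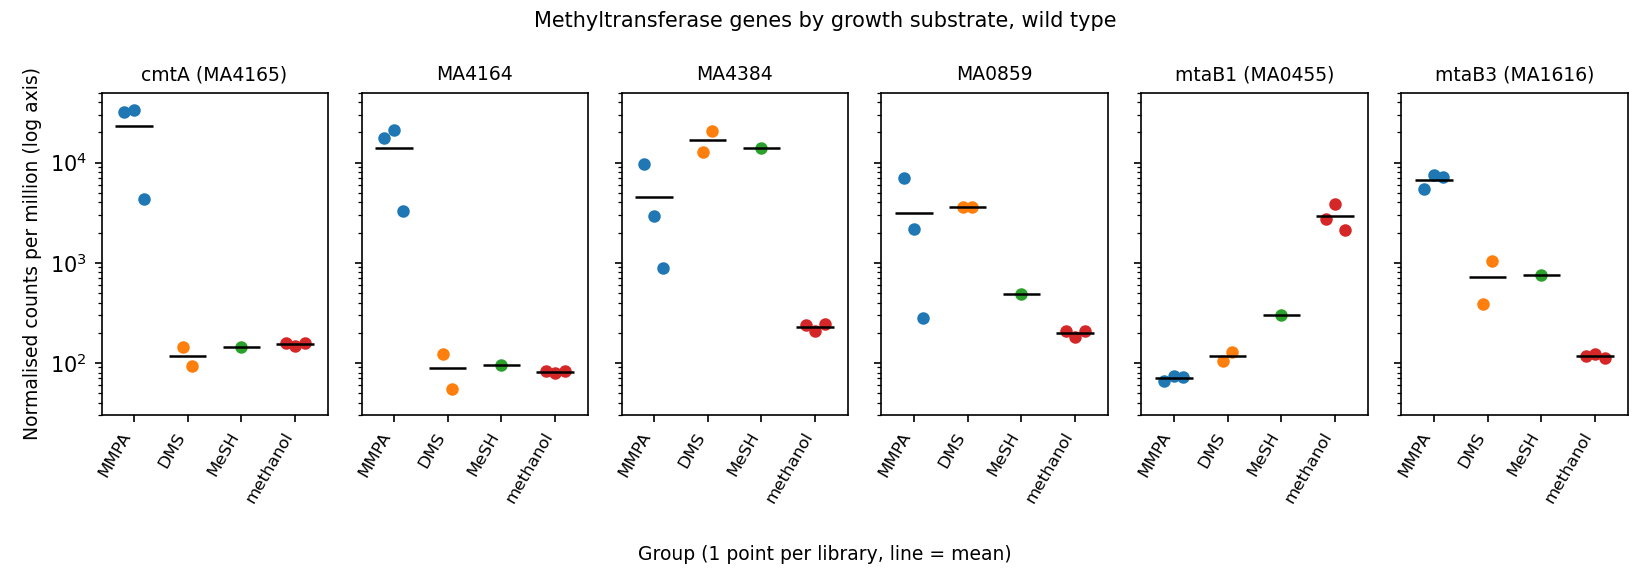
Levels of selected genes in each wild-type library, in CPM on a log axis, with a point per library and the group mean. MMPA libraries lay above MeOH libraries for cmtA, at 23347 against 154 CPM on average, and below them for mtaB1, at 70.3 against 2910 CPM.

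The comparison of DMS with MeOH asks the same of growth on DMS. The mts gene MA4384 was 72.5-fold higher on DMS, at 16716 ± 5540 (SD, n = 2) against 230 ± 20.0 CPM (n = 3), with a log2 fold change of 6.18 (SE 0.98, adjusted p = 0.0120). It missed the threshold without MeOH replicate 1 (adjusted p = 0.0630) or MeOH replicate 3 (adjusted p = 0.0631). MA0859 was 18.2-fold and MA4558 16.3-fold higher (adjusted p = 0.0381 and 0.0370), and both calls were lost when either DMS library was left out, with adjusted p values of 0.0886 and 0.101 without DMS replicate 2. MA3319 rose 60.1-fold (551 ± 75.7 against 9.43 ± 1.31 CPM, adjusted p = 1.30e-06), MA0158 by 4.29 (log2, SE 0.17), MA0157 by 4.09 (SE 0.22), MA2670 by 3.99 (SE 0.41), MA1629 by 2.92 (SE 0.24) and mtrG by 2.59 (SE 0.34). MA4565 rose by 5.78 (log2, SE 0.80), and by 3.51 without DMS replicate 2. The methanol genes MA0457 (-5.04, SE 0.52), mtaC1 (-4.91, SE 0.64) and mtaB1 (-4.69, SE 0.43) fell on DMS as on MMPA. MA0457 and mtaC1 had 0 counts in DMS replicate 2, which allows up to 3 counts. That library thus sets only a limit on their level, and the size of their folds rests on DMS replicate 1. The mtp locus had 0 of 4 genes past the threshold in edgeR's test, over all genes and adjusted over the list alone, and cmtA stood at 118 ± 36.0 CPM (adjusted p = 0.871).

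The 8 highest log2 fold changes the naming rule took on DMS belonged to genes whose SD between the DMS libraries exceeded the mean. All but MA1400 were among 9 genes that together held 39.5% of counts in DMS replicate 1 and 90.8% in DMS replicate 2. They were MA0803 (12.56), hemD (11.61), MA1803 (10.85), cam (9.24), hat (9.24), MA0615 (8.32), leuD_1 (8.20) and MA1400 (7.81). Without DMS replicate 2 the same values were 8.06, 6.92, 7.05, 5.29, 5.18, 4.18, 3.29 and 3.45, and without DMS replicate 1 they were 13.47, 12.52, 11.74, 10.13, 10.13, 9.23, 9.12 and 8.72. The gene mttP followed this pattern, at 5.92 and 2.003 without DMS replicate 2. Others that rose were hsp60-4 (4.10), mtaC3 (2.72), mtbA_1 (2.71), rpl7ae (2.46) and rpl39e (2.42). Without DMS replicate 2, mtaC3 stood at 1.87, mtaB3 at 1.69, cysK at 1.74 and mtbA_1 at 1.55. Without DMS replicate 1, mttP stood at 6.82, MA4565 at 6.86, MA2670 at 5.20, mtbA_1 at 3.33, rpl39e at 3.27 and atpH at 2.62. After the mtaB1 group, the lowest the naming rule took were MA1579 (-2.46), MA1056 (-1.75), MA1034 (-1.75), MA2406 (-1.39) and MA4182 (-1.37). DMS replicate 2 held 4 counts of MA1579, 1 of MA1034 and 0 of MA1056, where 0 allows up to 3. Without DMS replicate 1, MA1579 stood at -0.34 (adjusted p = 0.779) and MA1034 at -4.35, and the calls of MA1056 (adjusted p = 0.195), MA2406 (0.223) and MA4182 (0.374) were lost too. Without DMS replicate 2 that of MA1056 was also lost (0.0748). On the RPKM scale, where the median of all genes moved from 0.06 to -2.40, about as far as these genes did, the sign of mtaB3 (2.56), cysK (2.42), MA2718 (2.20), hspA (2.11), atpC_1 (2.02), atpH (1.99), ahpC (1.98), cdhE_1 (1.90), mtrA (1.88), cdhA_1 (1.84), MA3734 (1.82) and hmaA (1.42) was negative. Of these, MA3734 (1.82), mtrA (1.47), hspA (1.42), MA2718 (1.40), ahpC (1.36), cdhA_1 (1.25), cdhE_1 (1.23) and atpH (1.13) lost their call without DMS replicate 2.

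Of 4627 genes, 239 were higher and 106 lower on DMS, 216 and 83 of them by at least 2-fold. This split did not hold on the RPKM scale, where 32 were higher and 2011 lower. The count of 345 changed to 216 without DMS replicate 2, and to 63, 135 and 64 without MeOH replicate 1, 2 and 3. With either DMS library left out, the other is assumed to vary like the other groups, here and against MMPA. Of the 44 named genes past the threshold, 13 kept their call whichever library was left out. These were MA0157, MA0158, MA0457, MA0615, MA1629, MA1803, MA2670, MA3319, MA4565, cam, mtaB1, mtaC1 and mtrG. Without DMS replicate 1, 9 of the 44 calls were lost, and 15 were lost without DMS replicate 2, among them hsp60-4 (adjusted p = 0.0575) and mtbA_1 (adjusted p = 0.166). Without MeOH replicate 1, 2 or 3, 30, 19 and 29 calls were lost. Camera found 11 lists higher and 1 lower on DMS, but none with an estimated correlation (lowest adjusted p = 0.490), and fry called 6. Camera's lists were ribosomal proteins (1.54e-07), CO dehydrogenase and acetate genes (1.51e-06), the Mtr methyltransferase (7.70e-06), ATP synthase, methyl-coenzyme M reductase, the mts methyltransferases (0.000502), methyl oxidation, the Fpo dehydrogenase, chaperones and heat shock, oxidative stress and sulfur amino acid genes, with archaellum and chemotaxis lower. Fry's 6 were the mts methyltransferases, methyl-coenzyme M reductase, the Mtr methyltransferase, CO dehydrogenase and acetate genes, sulfur amino acid genes and oxidative stress. Among the lists that missed with fry were ribosomal proteins (fry adjusted p = 0.164) and ATP synthase (0.0862). Genes of the Mtr methyltransferase were higher in 6 of 8 (7 adjusted over the list alone), of methyl-coenzyme M reductase in 0 of 5 (5 adjusted over the list alone), of ATP synthase in 2 of 11 (10 adjusted over the list alone) and of ribosomal proteins in 7 of 46 (20 adjusted over the list alone).

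The MeSH group holds 1 library, assumed to vary like the other groups. In it MA2919 was 110-fold higher than on MeOH, at 4281 against 38.7 ± 2.26 CPM (SD, n = 3), with a log2 fold change of 6.79 (SE 0.56, adjusted p = 0.00155). MA3319 was 10.3-fold higher (log2 3.36, SE 0.20, adjusted p = 0.000198). These were the 2 of 10 named genes past the threshold that kept their call whichever MeOH library was left out. Higher too were MA4565 (log2 5.77), MA4240 (2.48), MA3734 (1.91), MA4244 (1.51), MA0158 (1.48) and hmaA (1.39), and lower were mtaB1 (-3.26) and MA0457 (-3.20). MA4384 was the gene with the most counts in the MeSH library, at 14082 CPM, but its adjusted p of 0.0630 missed the threshold. Adjusted over the list alone it was 1 of 3 mts methyltransferases that passed. In all, 10 genes were higher and 2 lower of 4627 tested, and 2, 6 and 3 genes passed without MeOH replicate 1, 2 and 3. Without DMS replicate 2, which takes part in the shared fit, 36 passed, 33 higher and 3 lower. Camera found 12 lists higher on MeSH, the most extreme being ribosomal proteins (adjusted p = 1.09e-14), whose adjusted p was 0.552 with an estimated correlation. No list passed with an estimated correlation or with fry.

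DMS and MMPA libraries share 1 name series, and their comparison asks how growth on the sulfur compounds differed. DMS replicate 1 and MMPA replicate 1 carry the same index and lane code, so they cannot come from 1 lane of 1 run. The file headers also name a read group for DMS replicate 1, and none for DMS replicate 2 or the MMPA libraries. Runs are not given, so what they add here, or beside dose within DMS, cannot be separated. On DMS, cmtA was 188-fold lower than on MMPA (118 ± 36.0 against 23347 ± 16460 CPM, log2 -7.55, SE 1.17, adjusted p = 0.00880), and MA4164 142-fold lower (log2 -7.15, SE 1.04). MA4166 was 64.7-fold lower, a call lost without DMS replicate 1, where the log2 fold change was -6.93 against -6.02 (adjusted p = 0.0919). Lower too were cdhB_2 (-3.69), mtaC3 (-3.58), cdhE_2 (-3.50), cdhA_2 (-3.50), cdhC_2 (-3.46), mtaB3 (-3.28) and cmtM_2 (-2.15), each kept whichever library was left out. Without DMS replicate 2 the values were -4.54 for mtaC3, -4.26 for mtaB3 and -2.81 for cmtM_2, and without DMS replicate 1 they were -8.15 for cmtA, -8.15 for MA4164, -4.43 for cdhB_2 and -1.35 for cmtM_2. Higher on DMS were MA2919 (213-fold, log2 7.74, SE 0.56), MA0158 (log2 2.85, SE 0.17), MA0157 (2.27, SE 0.21) and MA3319 (1.96, SE 0.18), each also kept, with MA2919 at 6.83 without DMS replicate 2. Other genes that lost their call when 1 library was left out were mtmC1 (-1.99), mttC_1 (-1.92), mttB_1 (-1.75), mtmB1 (-1.61), MA3734 (-1.26), mat_2 (-1.20), MA0658 (-1.11), hmaA (-1.06), mtmC (0.89), mtrG (1.61), MA1629 (1.78), MA2670 (1.98), pstS_1 (3.18) and mttP (5.76), and mtmC and mtrG were negative on the RPKM scale, where the median of all genes moved from 0.08 to -1.81, so these signs say nothing of the 2 genes apart from the scaling. Without DMS replicate 2, mttP stood at 1.74, pstS_1 at 1.31, mtmB1 at -2.33, mtmC1 at -2.86 and mtmC at 0.58. Without DMS replicate 1, mttP stood at 6.56, pstS_1 at 3.92, MA2670 at 3.09, mtmC at 1.63 and mtmC1 at -1.19. The genes abundant in the DMS libraries, MA0803 (12.85), MA1803 (11.40), hemD (10.53), cam (9.14), hat (8.49), MA0615 (8.32) and leuD_1 (7.12), were again high, and stood at 8.23, 7.50, 5.74, 5.08, 4.33, 4.07 and 2.10 without DMS replicate 2 and at 13.64, 12.18, 11.34, 9.93, 9.28, 9.11 and 7.93 without DMS replicate 1. Of these, MA0803 (adjusted p = 0.0762), hemD (0.0667), leuD_1 (0.0631) and hat (0.0526) lost their call without MMPA replicate 2.

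In all, 341 genes were higher and 292 lower on DMS than on MMPA, of 4627 tested. The split of these 633 genes moved to 208 and 327 with RLE normalization and to 18 and 371 on the RPKM scale, and the fit of the 2 groups alone gave 41 and 46. The count was 181 without DMS replicate 1, 974 without DMS replicate 2, 239 without MMPA replicate 2 and 1253 without MMPA replicate 3. Of 35 named genes past the threshold, 13 lost their call without DMS replicate 1, 2 without DMS replicate 2, 3 without MMPA replicate 1 and 12 without MMPA replicate 2. Camera found the mtp locus (adjusted p = 0.000378), CO dehydrogenase and acetate genes (5.66e-10), the Rnf complex (0.0128) and sulfur amino acid genes (0.00816) lower on DMS, and the Mtr methyltransferase (0.0362) and phosphate transport (0.00816) higher. None passed with an estimated correlation (lowest adjusted p = 0.538), and fry called 2. Without DMS replicate 1 the Rnf complex (0.248) and sulfur amino acid genes (0.294) missed the threshold, as did the Mtr methyltransferase without DMS replicate 2 (0.159) or MMPA replicate 3 (0.124). CO dehydrogenase and acetate genes were lower in 10 of 16 (14 adjusted over the list alone), and phosphate transport genes higher in 1 of 8 (7 adjusted over the list alone).

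The series text states a search for genes unique to each substrate. Against each of the other 3 wild-type groups, 105 genes were specifically higher on MMPA by at least 2-fold, led by cmtA, MA4164, MA4166, cdhB_2 and cdhE_2. On DMS 7 were, led by MA0158, MA0157, MA2670, MA3319 and MA1629. MA0158 and MA3319, and hmaA of the MMPA set, were also higher than on MeOH in all 3 sulfur groups. Specific here thus means highest on that substrate, not changed there alone. On MeSH the edgeR test gave 0, with 475 genes at an unadjusted p under 0.05 against DMS, and DESeq2 and limma also gave 0. In 50 simulations with unchanged groups, 0 genes met these rules. Few genes can be called where none is changed, so this result was nearly fixed in advance. Leaving out 1 library gave 11 to 231 MMPA-specific genes, with 38 without DMS replicate 1, 203 without DMS replicate 2, 62 without MMPA replicate 2, 231 without MMPA replicate 3, and 11, 17 and 11 without MeOH replicate 1, 2 and 3. For DMS the number was 70 and 30 without DMS replicate 1 and 2, 4 without MMPA replicate 2, and 0, 4 and 0 without MeOH replicate 1, 2 and 3. For MeSH it was 3 without DMS replicate 2.

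Genes higher than on MeOH in all 3 sulfur groups were MA3319, MA4565, MA3734, MA0158, hmaA, MA2920 and MA4240, the last 2 named after their values were seen. Membership rests in part on the MeSH group, 1 library assumed to vary like the other groups. Independent lists of the same sizes would share 0.138 genes. In simulations where all groups, MeOH included, were drawn from the MeOH means, 0.02 genes were shared on average and 1 at most. With no gene changed few calls can arise, so these simulations cannot show what shared controls add to lists of changed genes. mtaB1 and MA0457 were lower in all 3, where independent lists would share 0.0139 and the simulated groups shared 0. MMPA and DMS shared 173 higher genes (63.7 for independent lists) and 80 lower (32.2 for independent lists). The simulated unchanged groups here shared 0.02 on average and 1 at most higher, and 0 lower. For the same reason these values give no measure of what the shared controls add. Part of the excess may come from the 3 MeOH libraries that the comparisons share, since 3 controls cannot be split into sets of 2 or more each. The MeOH libraries also differ in name series from all sulfur libraries, so a difference between series could give such genes too and cannot be told apart. The number higher in all 3 was 1, 3 and 1 without MeOH replicate 1, 2 and 3, and 2 without MMPA replicate 2, against 62 without MMPA replicate 3, 21 without MMPA replicate 1, and 20 and 19 without DMS replicate 1 and 2. The genes lower in all 3 numbered 0, 1 and 1 without MeOH replicate 1, 2 and 3, and 1, 0 and 9 without MMPA replicate 1, 2 and 3. For MMPA and DMS, the numbers higher and lower were 97 and 53 without DMS replicate 2, 40 and 10 without MeOH replicate 1, 85 and 22 without MeOH replicate 2, 38 and 10 without MeOH replicate 3, 87 and 29 without MMPA replicate 2, and 359 and 137 without MMPA replicate 3.

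The comparison of the msrH deletion with its parent asks which genes differ between these strains during growth on trimethylamine with MMPA. The deleted gene, taken before the data were examined to be MA4167 (5088676 to 5089536 on the chromosome), was 209-fold lower in the deletion, at 1.22 ± 0.60 against 264 ± 16.9 CPM (SD, n = 3 each; log2 -7.71, SE 0.26, adjusted p = 6.47e-05). The deletion libraries held 13, 8 and 4 counts of MA4167, against 1947, 4144 and 1853 in the parent. The genes that rose most on MMPA fell in the deletion: MA4164 was 14.2-fold lower (200 ± 29.04 against 2836 ± 233 CPM, log2 -3.83, SE 0.17, adjusted p = 0.000165) and cmtA 13.4-fold lower (316 ± 21.5 against 4239 ± 492 CPM, log2 -3.74, SE 0.17, adjusted p = 0.000165). MA4166 was 3.97-fold lower (187 ± 54.5 against 742 ± 42.2 CPM, log2 -1.99, SE 0.21, adjusted p = 0.0354). That call was lost with deletion replicate 2 (adjusted p = 0.407) or 3 (0.104) or parent replicate 1 (0.202), 2 (0.265) or 3 (0.229) left out. The values of mtaB3 (-0.89, SE 0.12, adjusted p = 0.153) and mtaC3 (-0.97, SE 0.24, adjusted p = 0.724) did not pass. Both genes still lay lower in every deletion library than in every parent library. For mtaB3 the highest deletion library held 285 CPM and the lowest parent library 448, and for mtaC3 259 and 325. The mts genes MA4384 (-0.27), MA0859 (-0.13) and MA4558 (-0.19) did not pass either. The count of hpt was 0 in all 6 libraries, which allows up to 3 counts in each, and these limits cover counting error alone.

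MA4167, MA4164, cmtA and MA4166 were the 4 genes past the threshold of 4617 tested, and 0 were higher. As they lie together, loss of the msrH product cannot be told apart from an effect of the deletion on adjacent genes. The labels name the integrase cassette at hpt for the parent alone, so differences between the strains cannot be credited to msrH alone. At an unadjusted p under 0.05, 264 genes differed, 141 of them higher, and DESeq2 called 1 higher and 8 lower, and limma on the RPKM scale called 0 higher and 4 lower. The mtp locus was lower as a list, with 4 of 4 genes over all genes and adjusted over the list alone (camera adjusted p = 1.42e-18, and 0.0170 with an estimated correlation). This list holds MA4167, whose fall the deletion itself sets. With MA4167 left out, an alternative added after the results were seen, the adjusted p of the other 3 genes was 9.87e-14, and 0.0312 with an estimated correlation. Methanol methyltransferases had 0 of 9 genes past edgeR's threshold (2 lower adjusted over the list alone) and passed camera at 0.00483, with an adjusted p of 0.390 with an estimated correlation and 0.0754 without deletion replicate 1. Of the 4 genes lower in the deletion, 3 were among the 735 genes at least 2-fold higher on MMPA than on MeOH, where 0.637 would be by chance (two-sided Fisher's exact test, p = 0.0142, odds ratio 15.9). The 4 genes are the deleted gene and its neighbours in 1 locus, while the test takes genes as independent, so this p supports no overlap beyond that locus. Without deletion replicate 2 or 3, or any 1 parent library, MA4166 left the overlap and p was up to 0.0680. With DESeq2 the overlap held 7 of 8 lower genes, more than the 4 genes of the mtp locus.

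**Figure D2:**
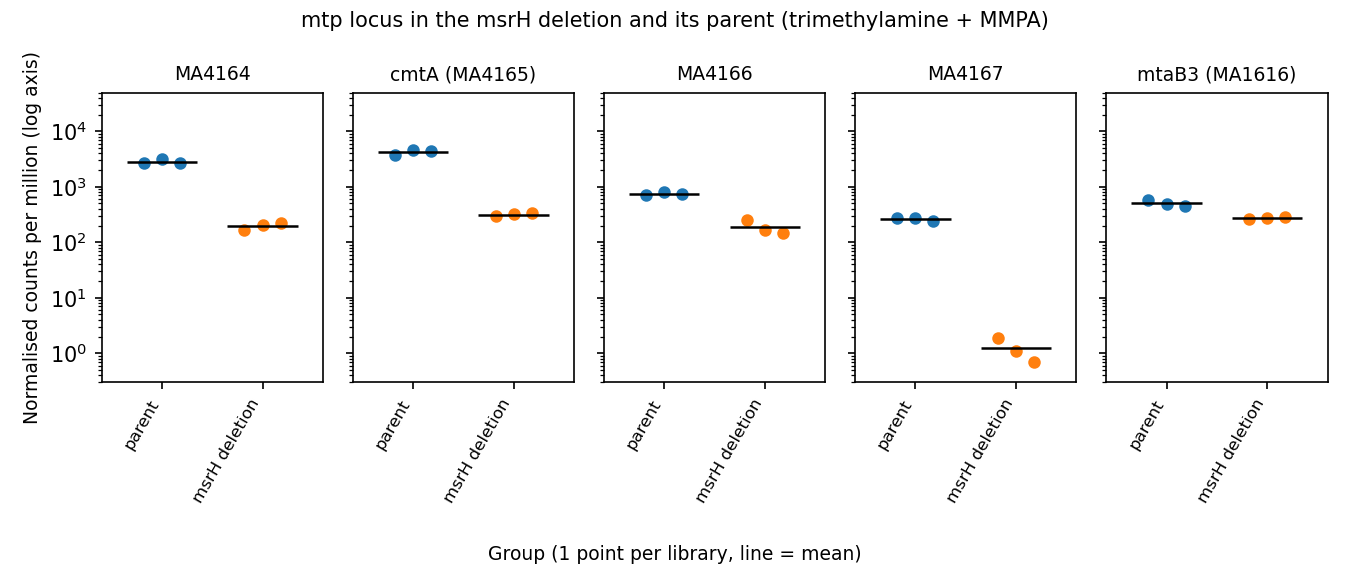
Levels of selected genes in each library of the parent and the msrH deletion strain, in CPM on a log axis, with a point per library and the group mean. MA4167, MA4164 and cmtA lay lower in all 3 deletion libraries than in all 3 parent libraries, at 1.22, 200 and 316 against 264, 2836 and 4239 CPM on average.

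The authors' deposited fold changes, which have the second group over the first and so the opposite sign, gave the same direction once turned for all 2637 genes past the threshold on MMPA against MeOH, all 345 on DMS, all 12 on MeSH and all 633 in DMS against MMPA. Both start from the same counts.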

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

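The tests of the genes that filled the DMS libraries and of the low genes in MMPA replicate 3 were chosen only after these results were seen.

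In the DMS libraries 9 genes, each with at least 100 counts in DMS replicate 2 and a share there at least 10 times that in any MMPA, MeSH or MeOH library, held 39.5% and 90.8% of counts, against at most 0.612% elsewhere. They were chosen after their values were seen, and MA3471 and MA4588 held most of these counts. Reads shared between gene copies are argued against, since at least 99.9966% of their reads had a single match, and so is an accident of DMS replicate 2 alone, since in replicate 1 their median lay 5.54 (log2) above the highest other library. A candidate explanation is 1 source present in both libraries in different amounts. The log2 ratio of replicate 2 to replicate 1 had an SD of 0.391 over the 9 genes, but ran from 0.951 (MA1803) to 2.09 (leuD_1). The ratio of MA3471 to MA4588 counts stood at 1.52 in replicate 1 and 1.49 in replicate 2. Whether that source is technical or a response of cells on DMS was not tested, and the dose (9 and 20 mM) stays open.

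In MMPA replicate 3, cmtA stood at 4360 CPM against 32105 and 33576 in the others, MA0859 at 280 against 6980 and 2184, and the methyl-coenzyme M reductase gene MA4550 at 12051 against 40431 and 34591. Mixing with RNA of methanol-grown cells is argued against: the share needed for cmtA is 87.1%, and the median of mtaB1, mtaC1 and MA0457 reached 2.75% of the level that share would bring. A library of another wild-type group is also argued against, as mtaB3, mtaC3 and the cdh genes lay at a median of 2.86 (log2) above the highest library of the other groups. The genes of both checks were picked after the values of the MMPA group, replicate 3 included, were seen. The choice may therefore favour these outcomes. A difference in growth stage may be involved and was not tested, since the labels give none per library.

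Some shares of counts outside the tested genes lay above the highest control library, in part by little, and no explanation of them was tested. With few control libraries, values above the highest can arise by chance. The rRNA had been subtracted with probes, and an earlier mapping, not described further, may have removed more of its reads. Its share is thus what was left and not its level in cells. The share of counts on rRNA genes was 0.00882% and 0.0290% in DMS replicates 1 and 2, 0.0177%, 0.0607% and 0.156% in MMPA replicates 1, 2 and 3, and 0.00140% in the MeSH library, against at most 0.000545% in MeOH libraries. The share on tRNA genes was 0.00268% in DMS replicate 2, 0.00150% and 0.00172% in MMPA replicates 2 and 3, and 0.00267% in the MeSH library, against at most 0.00144% in MeOH libraries. In msrH deletion replicate 1 the rRNA share was 0.00107% and the tRNA share 0.00102%, against at most 0.000872% and 0.000804% in parent libraries.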

How the results depend on the processing

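The alternatives with unique gene reads, with DMS replicate 2 and MMPA replicate 3 both left out, with MA3471 and MA4588 removed, with MA4167 left out of its lists, and, for MMPA and MeSH against MeOH only, with DMS replicate 2 left out of the shared fit were chosen only after the data were seen. No paired analysis was possible because replicate numbers were given in the order of the sample records and pair no libraries. The fits of 2 groups alone were not run for genes specific to a substrate or shared by 3 groups, since MeSH has 1 library. A lone DMS library left in its group was assumed to vary like the other groups. The cause was not tested where none is given.

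MMPA against MeOH kept its count of 2637 within 1.5 times in all alternatives run except a test against 2-fold (323), limma on log2(RPKM + 1) (40) and single libraries left out. The msrH deletion gave 3 or 4 genes, except with DESeq2 (9), and MA4167, MA4164 and cmtA kept their calls in all alternatives. No filter on low counts and rRNA and tRNA kept changed no count here by 1.5 times. Of 1168 values of 65 named genes for MMPA against MeOH, 1053 kept their call, 112 lost it and 3 changed sign. For DMS against MeOH these were 544, 146 and 12 of 702, for MeSH 93, 37 and 0 of 130, for DMS against MMPA 448, 73 and 2 of 523, and for the deletion 49, 7 and 0 of 56.

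With RLE normalization 11 genes, and with upper-quartile normalization 12, were higher in all 3 sulfur groups, and upper-quartile normalization gave 4 DMS-specific genes. The share of called genes that were higher moved from 46.8% to 30.2% for MMPA against MeOH with upper-quartile normalization. For DMS against MeOH it moved from 69.3% to 57.3% with upper-quartile normalization, and for DMS against MMPA from 53.9% to 38.9% with RLE normalization and 41.0% with DESeq2. Limma on log2(RPKM + 1) gave shares of 90.0% for MMPA and 1.57% for DMS against MeOH and 4.63% for DMS against MMPA, and the test against 2-fold gave 93.8% and 89.7% against MeOH. With 1 library left out the share ranged from 48.3% to 62.9% for MMPA against MeOH, from 62.0% to 82.5% for DMS against MeOH and from 27.2% to 58.0% for DMS against MMPA.

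DESeq2 gave 663 genes for DMS and 109 for MeSH against MeOH, 199 MMPA-specific and 47 DMS-specific genes, 73 genes higher and 6 lower in all 3 sulfur groups, and 357 higher and 124 lower on both MMPA and DMS. The test against 2-fold asks for more and gave 68 for DMS and 2 for MeSH against MeOH, 35 for DMS against MMPA, 0 MMPA-specific and 1 DMS-specific genes, 1 higher and 0 lower in all 3, and 27 higher and 3 lower on both.

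Limma on log2(RPKM + 1) gave 2043 for DMS and 3 for MeSH against MeOH, 389 for DMS against MMPA, 3 MMPA-specific genes, 1 higher and 0 lower in all 3, and 2 higher and 4 lower on both. RPKM carries no correction for a few abundant genes, and its median log2 fold change was -2.40 for DMS and -0.73 for MMPA against MeOH and -1.81 for DMS against MMPA, against 0.06, -0.10 and 0.08, a shift of all genes. All signs that changed did so there: mtaA_1 (-0.16), mtbA_2 (-0.23) and mtbC_2 (-0.0595) for MMPA against MeOH; MA2718 (-0.36), MA3734 (-0.69), ahpC (-0.52), atpC_1 (-0.40), atpH (-0.51), cdhA_1 (-0.69), cdhE_1 (-0.63), cysK (-0.11), hmaA (-1.09), hspA (-0.40), mtaB3 (-0.0428) and mtrA (-0.56) for DMS against MeOH; and mtmC (-0.56) and mtrG (-0.19) for DMS against MMPA.

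With the 2 groups alone, DMS against MMPA gave 87 genes, and 125 were lower on both MMPA and DMS. With DMS replicate 2 left out of the shared fit, MeSH against MeOH gave 36. Unique gene reads gave 19 for MeSH against MeOH, 3 DMS-specific genes and 12 higher in all 3. With DMS replicate 2 and MMPA replicate 3 both left out, DMS gave 661 and MeSH 744 against MeOH, DMS against MMPA 2023, the specific sets 330 (MMPA), 34 (DMS) and 6 (MeSH), the sets of all 3 groups 205 higher and 45 lower, and those of MMPA and DMS 315 higher and 205 lower. In that setting 12 lists passed for DMS against MMPA.

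Leaving out 1 library gave 1696 to 3193 genes for MMPA, 63 to 444 for DMS and 2 to 36 for MeSH against MeOH (2 to 6 with a MeOH library left out), 181 to 1253 for DMS against MMPA and 3 to 4 for the deletion. Specific genes ranged from 11 to 231 (MMPA), 0 to 70 (DMS) and 0 to 3 (MeSH), genes higher in all 3 from 1 to 62, genes lower in all 3 from 0 to 9, and those on both MMPA and DMS from 38 to 359 higher and 10 to 137 lower. Fisher's exact p for the overlap of the deletion and MMPA ranged from 0.00793 to 0.0680 with 1 library left out, and from 1.73e-06 to 0.0342 in the other alternatives. In the main test this overlap rests on neighbouring genes of 1 locus. With DESeq2 it held 7 of 8 lower genes, more than the 4 genes of that locus. Passing lists for the deletion ranged from 1 to 7.

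With an estimated correlation camera passed 0 lists for MMPA, DMS and MeSH against MeOH and for DMS against MMPA, and 1 for the deletion. With MA4167 left out of its lists 2 passed for the deletion, and 1 with an estimated correlation. Fry passed 6 for DMS and 0 for MeSH against MeOH, and 2 for DMS against MMPA. Of simulated 2-fold changes, 24% were recovered for DMS, 82% for MMPA and 48% for MeSH against MeOH, and the parts of depth, library number and spread in this were not separated. The simulation gave all groups the same spread per gene, which the real DMS libraries may exceed.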

Other observations

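The tests of neighbouring genes, of MMPA-specific genes in the deletion and of the library series were chosen only after the results were seen.

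Genes specific to MMPA often lay side by side, as cmtA with MA4164 and MA4166, or the cdh genes from cdhA_2 to cdhE_2. The 105 genes formed 22 adjacent pairs in the order of tested genes, where random draws of as many genes gave 2.36 on average and 10 at most (permutation test with 10000 draws, p = 0.0001, the smallest they can give). Shared transcripts are a candidate explanation, not tested beyond this count of 22.

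MMPA-specific genes outside the mtp locus may also be lower in the msrH deletion as a set, and the test left this open. Of 102 such genes, 70 were lower in the msrH deletion, with a median log2 fold change of -0.11 against 0.02 for all genes. Camera gave p = 4.07e-05 with the preset correlation and 0.0780 with an estimated one. edgeR's test called 0 of the 102, with 13 at an unadjusted p under 0.05, 12 of them lower.

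In parent replicate 1 some methylamine genes, picked after their values were seen, stood below the other parent libraries, with mttB_1 at 525 CPM against 2984 and 2681, mtbB_1 at 392 against 1831 and 1783, mttC_1 at 347 against 2908 and 2404, and mtmB1 at 1114 against 5087 and 4457. Others of the list did not, as mtbB_2 at 308 against 278 and 271, and mttB_2 at 272 against 241 and 264. In the deletion libraries mttB_1 stood at 2205, 2090 and 2963 CPM. Of the parent and deletion libraries, deletion replicate 1 differed most from its group, with Spearman's rho across genes of 0.914 and 0.902 to the others, which reached 0.991 with each other. Genes are not independent replicates.

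Over 4627 genes, the log2 fold change between MMPA and MeOH was nearly unrelated to gene length (Spearman's rho 0.0640). Whether longer genes were called more often was not tested, so this value cannot tell if length added to the number of calls. A difference between library series cannot be told apart from growth on methanol, since no methanol library has the series of the others. Of the genes at least 2-fold higher on MMPA than on MeOH, 96.6% were also higher than in the MeSH library and 85.3% higher than on DMS. These shares decide nothing, since the genes were chosen for high values in the same MMPA libraries and no value for unchanged groups was computed.

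For MMPA against MeOH, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one, gave as many genes: 2637, against 0 in the highest other. For the msrH deletion against its parent, the splits are again 10 and too few, and 1 gave as many genes as the real 4, against 0 in the highest other.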
